A study of Mus musculus with 23 samples.

How the data were processed

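Retinal organoids grown from mouse induced pluripotent stem cells of an Nrl-GFP line were profiled by RNA sequencing of directional poly(A) libraries. Per the submitters' labels, docosahexaenoic acid (DHA) or linoleic acid (LA) bound to bovine serum albumin (BSA), or BSA alone, was supplied from day 10, and FGF1 was supplied at 200 ng/ml from day 26. The medium itself also changed at day 26, so a contrast of days holds the change of medium as well as age. There were 23 libraries in 9 groups, with 2 libraries in each group at day 26 (BSA, LA, DHA), 3 libraries in each day 32 group without FGF1, 3 in BSA with FGF1, 3 in LA with FGF1 and 2 in DHA with FGF1. The labels describe them as 2 to 3 biological replicates.

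Per the submitters' processing notes, Trimmomatic 0.36, kallisto 0.45.0, edgeR and the genome build GRCm38.p6 were used; the notes give no order of steps and no edgeR version. The gene table and the transcript table deposited by the authors hold expected counts (estimated counts that are not whole numbers) for all 23 libraries, with 52143 genes and 136550 transcripts. Column totals of the 2 tables were checked and differed by at most a relative 1.3e-11. The third table deposited by the authors holds a signal in normalized CPM for 18 libraries, because 5 libraries were eliminated by the authors per the series labels, and its other columns hold gene positions and the number of transcripts per gene per the file headers. Gene names, identifiers and positions are those of the deposited files (GRCm38). GENCODE M21, which holds 134456 of the transcripts, was used for GC content, available for 51280 genes.

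All 23 libraries were tested together. Gene counts were rounded to whole numbers, filtered with filterByExpr of edgeR 4.0.16 on the 9 groups (21124 genes kept), scaled by TMM and fitted with the edgeR quasi-likelihood (QL) model with one mean per group (residual degrees of freedom 14). P values were adjusted by the Benjamini-Hochberg method (BH) over the genes tested, and a gene was counted as changed at an adjusted p under 0.05. Standard errors were derived from the log2 fold change and the F statistic, and 95% intervals from the t distribution, so both are approximate. CPM values in the text were scaled by TMM, and log2 CPM per library used a prior count of 2. R 4.3.3, limma 3.58.1, DESeq2 1.42.0, Python 3.11.15 and matplotlib 3.10.9 were used.

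The 19 comparisons, the 31 gene lists, the rule for naming genes and the first alternatives were chosen before the data were examined. After the libraries were found to fall into 12 deeper and 11 shallower ones, 5 comparisons were added: day 32 with FGF1 against day 26 within the 12 deeper libraries (20111 genes), FGF1 within the 11 shallower libraries (19484 genes), and DHA against BSA, LA against BSA and DHA against LA within blocks. A block held the libraries of one day, one FGF1 state and one replicate number, which keeps deeper and shallower libraries apart. The 5 added comparisons were therefore picked after the structure of the data was seen.

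Named genes were the 10 largest log2 differences per direction among changed genes for the averaged comparisons and the added day comparison, the 3 largest per direction for the others, and the 3 smallest p values where no gene passed, each with an average log2 CPM of at least 1 and a symbol that is not a predicted-gene name. Retinal, FGF-response and lipid genes fixed beforehand and up to 4 members per list with the smallest p were named without this floor, so that Angptl4 (average log2 CPM −0.52) is named below it. Gene lists of 10 to 27 genes were written from general knowledge and tested with camera of limma (preset correlation 0.01), with BH over the 31 lists. Each was also tested by camera with an estimated correlation and by fry, and the number of members changed is given after adjustment over all genes and over the list alone. For the fatty acid comparisons within blocks, mean list scores were also compared by an exact permutation of media within strata of day, FGF1 state and library set, where the shallower libraries kept and left out by the authors formed separate sets.

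Alternatives were RLE size factors, no filter on low counts, DESeq2, limma voom with sample quality weights, a replicate block, the 18 libraries kept by the authors, the groups of the comparison only, leaving out 1 library at a time, library set as a term, GC offsets (lowess span 0.3 per library), libraries of one depth set only, and a replicate block within each day and FGF1 state. Counts were called moved at a ratio over 1.5. Group labels were also split in up to 100 other ways. Residuals of libraries with the same replicate number were correlated between groups. For DHA and LA at day 32 without FGF1 every pair was over 0.1 (r of 0.228, 0.546 and 0.352), so the numbers were taken to pair these libraries. Yet replicate 1 of both groups was left out by the authors, so traits of the library sets may also give these correlations. Principal components were computed on log2 CPM of the kept genes.

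The depth per library was 16029580 to 20510550 counts in the deeper and 10405663 to 11888224 in the shallower libraries. Replicates of a group differed by more than counting noise. The chi-square per degree of freedom was 11.5 to 94.4 for pairs within a library set and up to 260 for pairs across sets. The spread between libraries therefore limited the precision more than counting noise did. Among genes with an average log2 CPM of at least 1, the median standard error of a log2 difference was 0.489 for the media at day 26 and 0.403 at day 32, 0.243 for FGF1 averaged over media, 0.262 for day averaged over media, 0.130 for day within the deeper libraries, 0.159 for DHA against LA within blocks, and 0.602 to 0.634 for differences between effects.

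Power was tested on simulated data in which 200 genes were given known changes on these libraries (67 at 1.5-fold, 67 at 2-fold and 66 at 4-fold). The edgeR fit called 0%, 0% and 6.06% of them for DHA against BSA at day 26, 0%, 1.49% and 31.8% for DHA against BSA at day 32, and 0%, 2.99% and 45.5% for FGF1 in DHA. It called 4.48%, 32.8% and 84.8% for FGF1 averaged over media, 4.48%, 23.9% and 87.9% for day averaged over media, 55.2%, 91.0% and 100% for day within the deeper libraries, and 5.97%, 16.4% and 86.4% for DHA against LA within blocks. False calls numbered at most 8 by edgeR and 21 to 47 by DESeq2. The spread was simulated from the fit with a mean per group, where some groups mix library sets. The shares for the comparison within blocks, which keeps the sets apart, and for DHA against BSA at either day may therefore be too low.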

Results

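The libraries fell into 2 sets by depth that the labels do not name. Of the 23 libraries, 12 were deeper (16029580 to 20510550 counts) and 11 were shallower (10405663 to 11888224), with no library in between. The deeper libraries were all 6 of day 26 and replicates 1 and 2 of each day 32 group with FGF1, and the shallower ones were all 9 of day 32 without FGF1 and replicate 3 of BSA with FGF1 and of LA with FGF1. On average 27344 genes had at least 1 count in the deeper libraries, against 23494 in the 6 shallower libraries kept by the authors. The share of mitochondrial transcripts was 3.59% (SD 0.413) in the 12 deeper libraries, 8.39% (SD 2.23) in the 6 kept shallower libraries and 10.8% (SD 1.84) in the other 5 shallower libraries. The slope of log2 CPM on GC content, per 10 percentage points, was 0.839, −0.838 and −1.01 in the same 3 sets. The first principal component held 61.3% of the variance and separated the 2 depth sets, and the second held 7.06%. Day 26 against day 32 without FGF1 was therefore also deeper against shallower, and so was most of the contrast of FGF1 against no FGF1. Only the 2 shallower FGF1 libraries, both among the 5 that the authors left out, break this overlap. Values within one set of libraries are given for FGF1 and for DHA against LA with FGF1, and day 32 with FGF1 was compared with day 26 within the deeper libraries. FGF1 in single media, day without FGF1 and DHA with FGF1 against BSA are given pooled.

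The 5 libraries that the authors left out of their normalized table carried transcripts that the others nearly lacked. Eif2s3y, a Y-linked translation factor gene, averaged 46.6 CPM in them (SD 13.6, n = 5, range 24.7 to 58.0) and was at most 0.925 CPM elsewhere. Ddx3y, a Y-linked RNA helicase gene, averaged 15.7 CPM, and Meg3, an imprinted long noncoding RNA gene, averaged 235 CPM (SD 108, n = 5, range 115 to 380) against at most 7.90 CPM in any other library. Against the 6 kept shallower libraries, 55 genes were higher and 1 was lower in these 5 libraries (edgeR QL, BH, 19484 genes), and 4 of the 56 were X- or Y-linked. The log2 difference was 6.98 (SE 0.335) for Eif2s3y, 4.88 for Ddx3y and 6.19 for Meg3. Higher genes also included Rps3a2 (9.61), Rian (6.05) and pseudogenes such as Rps2-ps10 (4.93), and the lower gene was Grb10 (−1.62). Uty and Kdm5d, which are also Y-linked, did not pass, at 2.86 (adjusted p = 0.222) and −0.58, and Xist, the X-inactivation RNA, differed by −0.10. All 5 libraries stayed in the fits unless stated otherwise, and this contrast was defined after the structure was seen.

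At day 26 the photoreceptor genes Rcvrn and Nrl were lowest in both DHA libraries, though neither passed the test. Rcvrn, the recoverin gene, stood at 12.5 ± 0.541 CPM in BSA, 16.2 ± 5.44 in LA and 8.75 ± 0.363 in DHA (n = 2 each). Cpt1a, a gene of fatty acid oxidation, stood at 73.1 ± 1.67, 88.9 ± 6.26 and 51.5 ± 4.99 CPM. With edgeR QL and BH, 0 of 21124 genes differed for DHA against BSA (61 with unadjusted p under 0.05), 0 for LA against BSA (89) and 0 for DHA against LA (101). DESeq2 called 2, 1 and 2 genes in these comparisons, and limma voom called 0 in each. For DHA against LA, the log2 difference was −0.56 [95% interval −1.14, 0.03] for Nrl, the rod fate factor, −0.89 [−1.87, 0.10] for Rcvrn, −0.79 [−1.53, −0.05] for Cpt1a and −0.35 [−2.24, 1.54] for Fads2, a desaturase gene, each with an adjusted p of 1.00. The genes with the smallest p were Apol7e (−8.84, listed at 0 CPM in both DHA libraries, so that the value depends on the prior count), Myocd (−1.90) and Icam1 (1.42) for DHA against BSA, Gpr149 (2.06), Rab7b (2.35) and Smco3 (1.55) for LA against BSA, and Gpr149 (−1.98), Bhlhe23 (−3.29) and Myocd (−2.19) for DHA against LA. With 2 libraries per group the median interval reached 1.05 log2 units to each side, and only 6.06% of simulated 4-fold changes were found. The spread behind both values came from all 9 groups, some of which mix library sets. Chi-square per degree of freedom was 243 to 260 for pairs across sets with FGF1, against 11.5 to 39.1 at day 26. The interval may thus be too wide, and the share too low, for day 26 alone.

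Photoreceptor lists leaned towards LA at day 26. Between DHA and LA the genes shared by rods and cones were lower in DHA (median log2 difference −0.46, camera adjusted p = 3.6e-13, 0 of 26 members past the test, also over the list alone). This list alone held with an estimated correlation (adjusted p = 0.00148), though not by fry (adjusted p = 0.105). It did not hold with an estimated correlation in the 18 libraries kept by the authors (adjusted p = 0.0713) or within the deeper libraries alone (adjusted p = 0.449). Rod genes (median −0.58, adjusted p = 2.4e-11) and cone genes (−0.54, adjusted p = 6.5e-07) leaned the same way, each with an adjusted p = 0.0785 with an estimated correlation. For LA against BSA, 14 of 31 lists passed camera, among them mesenchyme and fibroblasts (median 1.32, adjusted p = 3.8e-10), pigment epithelium (0.99, adjusted p = 4.5e-06) and rods (0.35, adjusted p = 2.6e-06). With an estimated correlation their adjusted p values were 0.0836, 0.169 and 0.216. For DHA against BSA, 13 lists passed, led by pigment epithelium (0.78, adjusted p = 3.4e-07, and adjusted p = 0.204 with an estimated correlation) and by the shared photoreceptor genes (−0.17, adjusted p = 1.3e-04, and 0.153). Of the 12 lists past camera for DHA against LA, 1 held with an estimated correlation, and 0 lists held for the other pair of comparisons.

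At day 32 without FGF1 the rod gene Nrl differed between the fatty acids by less than the spread of the DHA libraries. Nrl stood at 889 ± 26.1 CPM in BSA, 834 ± 121 in LA and 789 ± 239 in DHA (n = 3 each). Angptl4, a lipase inhibitor gene induced by fatty acids through PPAR receptors, stood at 0.829 ± 0.670, 0.210 ± 0.114 and 0.0570 ± 0.0988 CPM. With edgeR QL and BH, 0 of 21124 genes differed for DHA against BSA (548 with unadjusted p under 0.05), 0 for LA against BSA (548) and 0 for DHA against LA (665), and DESeq2 called 5, 2 and 7 genes, and limma voom 0 in each. A replicate block within each day and FGF1 state gave 2 genes for DHA against LA, both higher in DHA. Angptl4 differed by −3.54 [−5.42, −1.65] between DHA and BSA and passed only over the list of fatty acid oxidation and PPAR targets alone (adjusted p = 0.0207). It stood at 0 to 0.171 CPM in the DHA libraries, so the value lies near the floor and depends on the prior count. LA against BSA leaned the same way for Angptl4 (−1.96 [−3.57, −0.34]) and did not pass over all genes. For DHA against LA, the difference was −0.08 [−0.56, 0.40] for Nrl, 0.06 [−0.33, 0.45] for Crx, the photoreceptor fate factor, and 0.02 [−0.75, 0.79] for Hmgcs1, the cholesterol synthesis gene, each with an adjusted p of 1.00. Genes with the smallest p were Abca13 (3.19), Hspa12b (1.79) and Bmp2 (−1.54) for DHA against BSA, Olfr1221 (−1.86), Cplane1 (1.47) and Aim2 (2.02) for LA against BSA, and Mertk (−1.39), Abca13 (2.93) and Nos1ap (1.31) for DHA against LA. The median interval reached 0.864 to each side, and 31.8% of simulated 4-fold changes were found for DHA against BSA.

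For DHA against BSA at day 32, 9 lists passed camera (1 higher, 8 lower), against 6 (3 higher, 3 lower) in the 18 libraries kept by the authors. Values from all libraries follow. Retinoid metabolism (median −0.49, adjusted p = 5.6e-04), pigment epithelium (−0.74, adjusted p = 9.8e-04) and mesenchyme (−0.66, adjusted p = 9.8e-04) were lower, and bipolar genes (0.33, adjusted p = 0.00901) were higher. With an estimated correlation the adjusted p values were 0.307, 0.405, 0.405 and 0.183. Tyr, the melanin synthesis gene, was the 1 pigment epithelium member past the test over the list alone (−3.49, adjusted p = 0.0403). For LA against BSA, 0 lists passed. For DHA against LA, 6 lists passed, all lower in DHA and led by mesenchyme (−0.94, adjusted p = 0.0200, and 0.465 with an estimated correlation). The 18 libraries kept by the authors gave 1 list, mesenchyme (adjusted p = 0.0442, and 0.902 with an estimated correlation), and the replicate block gave 8, of which 2 were higher, with 0 past an estimated correlation.

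With FGF1 at day 32, connective tissue and pigment cell genes leaned lower in organoids on DHA than on LA. Rod genes and genes shared by rods and cones leaned higher, while the cone genes Opn1sw (−1.85 [−3.90, 0.20]) and Arr3 (−0.86 [−1.97, 0.25]) leaned lower without passing. Dcn, Lum and the collagen genes Col3a1 and Col1a2, made by fibroblasts, were lower when adjusted over their list alone, as were the melanin synthesis genes Tyr, Tyrp1 and Pmel. Nrl stood at 891.9 ± 90.0 CPM in DHA (n = 2) and 566 ± 49.4 in LA (n = 3). Over all genes, 0 of 21124 passed (edgeR QL, BH, 719 with unadjusted p under 0.05), while DESeq2 called 54 (4 higher, 50 lower) and limma voom 38 (4 higher, 34 lower). The mesenchyme list fell by camera (median −2.62, adjusted p = 2.4e-11, and 0.0444 with an estimated correlation), with 6 of 15 members lower over the list alone, including Dcn (−6.01), Lum (−5.93), Col3a1 (−5.14) and Col1a2 (−2.62). The ciliary margin list was lower too (median −1.26, adjusted p = 6.3e-08, and 0.0444 with an estimated correlation), with 3 members lower over the list alone (Otx1, Gja1 and Msx1). Fry gave adjusted p = 0.0577 for both. Pigment epithelium genes (median −1.53, adjusted p = 1.5e-05) included Tyr (−5.66), Tyrp1 (−4.76) and Pmel (−4.28), past the test over the list alone, but the list gave adjusted p = 0.178 with an estimated correlation. Shared photoreceptor genes rose (median 0.51, adjusted p = 4.9e-07), which held with an estimated correlation (adjusted p = 0.0370) and by fry (adjusted p = 0.0164), while rod genes (0.75, adjusted p = 3.3e-07) gave adjusted p = 0.198 with an estimated correlation. In all, 11 lists passed camera, and Sema6d (−1.68), Lgi1 (−2.64) and Ptx3 (−2.42) had the smallest p among genes. Of the 3 LA libraries 1 was shallower and both DHA libraries were deeper, so this comparison mixes the sets. Within the deeper libraries alone, 2 genes passed, both lower in DHA (1507 with unadjusted p under 0.05). There mesenchyme (median −2.23), ciliary margin (−1.30) and shared photoreceptor genes (0.47) passed camera (adjusted p = 3.0e-11, 5.7e-08 and 2.5e-11). With an estimated correlation (adjusted p = 0.185 each) and by fry (adjusted p = 0.0884 each) they did not pass. In the 18 libraries kept by the authors the 3 lists gave adjusted p = 0.0501 each with an estimated correlation, and 0 lists passed by fry.

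Pooled over both days and FGF1 states, Opn1sw, Angptl4 and Scd1 leaned lower in DHA than in LA, and no gene passed the test. This average joins day 26, where the shared photoreceptor genes leaned lower in DHA (median −0.46), with day 32 with FGF1, where they leaned higher (median 0.51). At day 26 DHA against LA gave −1.21 for Opn1sw, −0.40 for Scd1 and −0.875 for Angptl4. At day 32 without FGF1 the differences were −0.06 for Opn1sw, −0.01 for Scd1 and −1.58 for Angptl4. With FGF1 the difference was −1.85 for Opn1sw. Within blocks over all 23 libraries, the log2 difference of DHA against LA was 0.00 [−0.31, 0.32] for Nrl, 0.09 [−0.12, 0.31] for Crx, 0.16 [−0.27, 0.59] for Rcvrn, −0.02 [−0.64, 0.60] for Fads2, −0.09 [−0.42, 0.24] for Cpt1a, −0.10 [−0.52, 0.32] for Plin2, the lipid droplet coat gene, and 0.00 [−0.24, 0.24] for Hmgcs1. Intervals that left out 0 before adjustment were those of Scd1, the stearoyl-CoA desaturase gene (−0.32 [−0.56, −0.07]), of Angptl4 (−1.15 [−2.24, −0.06]) and of Opn1sw, the short-wave cone pigment gene (−0.97 [−1.76, −0.18]), all with an adjusted p of 1.00. With edgeR QL and BH, 0 of 21124 genes passed (999 with unadjusted p under 0.05), DESeq2 called 10, and limma voom called 125 (22 higher, 103 lower). Smoc2 (−1.46 [−2.09, −0.82]), Lox (−1.19 [−1.75, −0.63]), which both act in the extracellular matrix, and Pla2g7 (−0.60 [−0.88, −0.31]) had the smallest p (adjusted p = 0.901 each). The median interval reached 0.344 to each side, and 16.4% of simulated 2-fold and 86.4% of simulated 4-fold changes were found. These shares may be too low, since the simulated spread also held the differences between library sets that blocks remove. For DHA against BSA 0 genes passed (453 unadjusted, DESeq2 2, limma voom 0), with Angptl4 at −1.52 [−2.61, −0.43], and the smallest p values belonged to Fat4 (−0.44), Hmcn1 (−0.80) and Pcna-ps2 (2.28), a pseudogene that was higher in the 5 left-out libraries than in the 6 kept shallower ones (5.62, adjusted p = 0.00414). For LA against BSA 0 genes passed (709 unadjusted, DESeq2 12, limma voom 48, of which 47 higher), with Scd1 at 0.26 [0.02, 0.49], and with Slc26a7 (1.32), Pla2g7 (0.55) and Rgs4 (0.77) at the smallest p.

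Within blocks the mesenchyme list had the smallest camera p of the 31 lists for DHA against LA. Its median log2 difference of DHA against LA was −1.26 (camera adjusted p = 2.6e-11, but adjusted p = 0.116 with an estimated correlation and 0.0824 by fry), and 7 of 15 members were lower over the list alone, among them Fbn1 (−0.92), Col1a2 (−1.38), Col1a1 (−1.85) and Col3a1 (−2.19). Its mean log2 CPM per library was 3.37 (SD 0.756, n = 3) in LA with FGF1 and 1.24 (SD 0.0494, n = 2) in DHA with FGF1, 2.33 (SD 0.726) and 1.60 (SD 0.733) at day 32 without FGF1 (n = 3 each), and 2.26 (SD 0.413) and 1.60 (SD 0.392) at day 26 (n = 2 each). BSA gave 2.22 (SD 1.11), 2.54 (SD 0.308) and 1.12 (SD 1.06) in the same order. An exact permutation of DHA and LA within strata (432 arrangements of 14 libraries) gave a difference of −1.14 with p = 0.0185, and 0.287 after adjustment over 31 lists. Ganglion cell genes were also lower in DHA (median −0.20, adjusted p = 1.2e-05, and 0.116 with an estimated correlation), with Slc17a6 as the 1 member past the test over the list alone (−1.34), and gave an exact permutation p = 0.00926 and 0.287 after adjustment. Fatty acid oxidation and PPAR targets were lower by a median of −0.12 (adjusted p = 2.3e-05, and 0.247 with an estimated correlation). In all 12 lists passed camera for DHA against LA, 8 for DHA against BSA and 6 for LA against BSA, led there by mesenchyme (0.75, adjusted p = 2.5e-05, and 0.638 with an estimated correlation), and 0 held with an estimated correlation or by fry. The lists past the exact permutation test after adjustment over 31 lists numbered 0 for each pair of media.

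FGF1, supplied from day 26, coincided with less RNA of the cholesterol synthesis gene Hmgcs1 in the pooled libraries, but not among the shallower libraries compared with each other. Averaged over media, 5690 genes were higher and 3846 lower with FGF1 (9536 of 21124, edgeR QL, BH). Hmgcs1 fell by 0.73 (SE 0.218, adjusted p = 0.0148). Opn1sw (1.52), Fads2 (1.13), Angptl4 (1.35), Rlbp1, a Müller glia gene (0.69), and Etv5, a target of FGF signalling (0.34, adjusted p = 0.0499), rose. Spry4 and Dusp6, feedback inhibitors induced by FGF, did not pass (0.44, adjusted p = 0.0665, and 0.25, adjusted p = 0.168), nor did Nrl (−0.25), Crx (−0.23), Gnat1 (0.56) and Rcvrn (0.31). Within the 11 shallower libraries, 2 with FGF1 (both left out by the authors) and 9 without, 0 of 19484 genes passed (380 with unadjusted p under 0.05, DESeq2 10, limma voom 0), and the differences were 0.29 for Spry4, 0.39 for Dusp6, 0.31 for Etv5, 0.14 for Rlbp1, 0.01 (SE 0.247) for Hmgcs1, −0.59 (SE 0.859) for Fads2, 1.06 (SE 0.751) for Opn1sw and 1.31 (SE 1.24) for Angptl4, all with an adjusted p of 1.00. Hmgcs1 stood at 184 ± 13.3 CPM in the 6 deeper FGF1 libraries, 425 ± 4.35 in the 2 shallower ones and 393 ± 66.7 in the 9 libraries without FGF1. With library set as a term, 0 genes passed for FGF1 averaged over media (1274 with unadjusted p under 0.05), so the pooled count is a contrast of sets as much as of FGF1.

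The largest pooled FGF1 differences, which also compare library sets, included pseudogenes, whose reads may be shared with other loci. They were AY036118 (12.76), Rpl10a-ps1 (10.00), Pgam1-ps2 (9.49), Mrip-ps (8.53), Trex1 (7.70), Oaz1-ps (7.57), Rpl36 (6.27), Nrarp (6.20), Nadk2 (6.12) and Hgs (5.94) among higher genes. Lower genes were Hist2h3c1 (−4.74), Rpl3-ps1 (−3.47), Rps27a-ps2 (−2.08), Pkhd1l1 (−1.96), Xist (−1.86), Cd247 (−1.81), Itgbl1 (−1.76), Akr1c19 (−1.74), Mkks (−1.74) and Bc1 (−1.74). Within LA with FGF1, where 1 of 3 libraries was shallower, AY036118 ranged from 0 to 260 CPM, Rpl36 from 0.440 to 99.1 and Mkks from 9.76 to 128. With library set as a term Pgam1-ps2, Rpl36, Nadk2, Hgs, Rpl3-ps1, Cd247 and Mkks changed sign. AY036118, Rpl10a-ps1, Pgam1-ps2, Mrip-ps, Trex1, Oaz1-ps, Nrarp, Nadk2 and Hist2h3c1 were at 0 CPM in all libraries of at least 1 group compared, so their fitted values depend on the prior count and bound nothing. Nadk2 and Hgs have more than one record in the annotation and are uncertain. Camera passed 0 of 31 lists for the averaged FGF1 effect. Fry passed 6, led by the primary cilium (median −0.25, adjusted p = 0.00370), lens (1.60, adjusted p = 0.00806) and FGF and ERK feedback targets (0.35, adjusted p = 0.00806), but 0 with library set as a term. Camera passed 3 within the shallower libraries: shared photoreceptor genes (median −0.20, adjusted p = 0.0106), amacrine genes (−0.34, adjusted p = 9.8e-04) and mesenchyme (0.82, adjusted p = 0.00975), with adjusted p values of 0.575, 0.575 and 0.622 with an estimated correlation. Among genes of the shallower libraries, Rps27a-ps2 (−8.58, a pseudogene at 0 CPM in both FGF1 libraries), Pde3b (1.12) and Arid3b (−1.30) had the smallest p. In single media 0 genes passed: in BSA (2509 with unadjusted p under 0.05, DESeq2 18, limma voom 10660), in LA (5100, DESeq2 1727, limma voom 11464) and in DHA (7596, DESeq2 4420, limma voom 10583). The smallest p belonged to Hspa12b (2.01), Fam198b (−2.42) and Gtse1 (2.15) in BSA, Pgpep1 (1.59), Nos1ap (1.59) and Gtse1 (2.66) in LA, and Scn3a (−1.42), Ncaph2 (95% interval 0.69 to 1.71) and Slitrk4 (−2.21) in DHA. In LA the count was 2 without LA replicate 2 and 7936 without replicate 3 of LA with FGF1, and in DHA it was 5752 without DHA replicate 2 and 1 without replicate 1 of DHA with FGF1.

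Between day 26 and day 32 many genes of rods, bipolar cells and Müller glia rose and many genes of dividing progenitors fell. Within the 12 deeper libraries, 6 of day 26 and 6 of day 32 with FGF1, depth does not part the days, but age, the change of medium and FGF1 act together. Gnat1, the rod transducin gene, rose from 4.31 ± 0.984 to 110 ± 67.3 CPM and Rcvrn, a calcium sensor gene of photoreceptors, from 12.5 ± 4.13 to 247 ± 93.0 (n = 6 each). Grm6, the glutamate receptor gene of ON bipolar cells, rose from 0.839 ± 0.822 to 79.5 ± 14.6 CPM, and Hes5, a Notch target gene of progenitors, fell from 34.5 ± 8.02 to 2.73 ± 1.28. With edgeR QL and BH, 2960 of 20111 genes were higher and 2837 lower (5797 in all, 7930 with unadjusted p under 0.05). Of these 5797 genes, 5542 (95.6%) were also among the 5894 called by DESeq2 and 5539 (95.5%) among the 5704 called by limma voom, all with the same sign. Leaving out 1 library gave 4373 to 5922 genes.

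Full statistics for the leading genes follow, with GRCm38 positions and identifiers. Rcvrn (ENSMUSG00000020907, chromosome 11, 67695326 to 67703333) rose by 4.33 log2 units (SE 0.215, adjusted p = 4.6e-07) and Gnat1 (ENSMUSG00000034837, chromosome 9, 107674474 to 107679712) by 4.62 (SE 0.391, adjusted p = 7.4e-05). Grm6 (ENSMUSG00000000617, chromosome 11, 50850685 to 50866208) rose by 6.77 (SE 0.304, adjusted p = 3.6e-07) and Bhlhe23, a bipolar fate factor gene (ENSMUSG00000045493, chromosome 2, 180774381 to 180776900), by 6.74 (SE 0.271, adjusted p = 3.3e-08). Edn2, an endothelin gene made by stressed photoreceptors (ENSMUSG00000028635, chromosome 4, 120161206 to 120167360), rose by 7.53 (SE 0.717, adjusted p = 5.2e-05). Fgf2, a growth factor gene (ENSMUSG00000037225, chromosome 3, 37348346 to 37410108), rose by 6.20 (SE 0.425, adjusted p = 2.4e-05). Hes5 (ENSMUSG00000048001, chromosome 4, 154960923 to 154962371) fell by 3.69 (SE 0.247, adjusted p = 2.8e-06) and Krt73, a keratin gene (ENSMUSG00000063661, chromosome 15, 101793308 to 101802346), by 5.96 (SE 0.320, adjusted p = 2.6e-07). Fgf15, a progenitor growth factor gene (ENSMUSG00000031073, chromosome 7, 144896531 to 144900953), fell by 3.53 (SE 0.477, adjusted p = 8.3e-04).

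The other genes with the largest rises were Slc24a1 (6.14), the rod sodium-calcium exchanger gene, Gabrr1 (5.71), a GABA receptor gene of bipolar cells, Bcl3 (5.10), Guca1b (4.98), Tnnt2 (4.93) and Kcng4 (4.83). Guca1b has 2 records in the annotation and is uncertain. Besides Krt73, Hes5 and Fgf15, the largest falls were those of Ecel1 (−4.24), AA623943 (−3.48), Gulo (−3.36), Abi3 (−3.36), Dnaic1 (−3.23), Tmem92 (−3.20) and Emilin3 (−3.19). Among genes named before the data were examined, Rlbp1 (2.03), Spry4 (1.48), Dusp6 (1.46), Etv5 (1.06) and Cpt1a (0.99) rose, while Opn1sw (−2.56, adjusted p = 0.0144), Plin2 (−1.15), Hmgcs1 (−1.09) and Pax6 (−0.59), an eye field and amacrine factor gene, fell. Opn1sw lost its call without replicate 2 of BSA with FGF1 (−2.44), replicate 1 of LA with FGF1 (−2.51), replicate 2 of LA with FGF1 (−2.62) or replicate 2 of DHA with FGF1 (−2.36). The photoreceptor fate factors did not pass: Nrl differed by 0.23 (adjusted p = 0.157), Nr2e3 by 0.05 (adjusted p = 0.753) and Crx by 0.06 (adjusted p = 0.705), and the cone arrestin gene Arr3 by 0.03 (adjusted p = 0.935). Fads2 (0.05), Scd1 (0.12) and Angptl4 (−0.13) did not pass either.

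**Figure D1:**
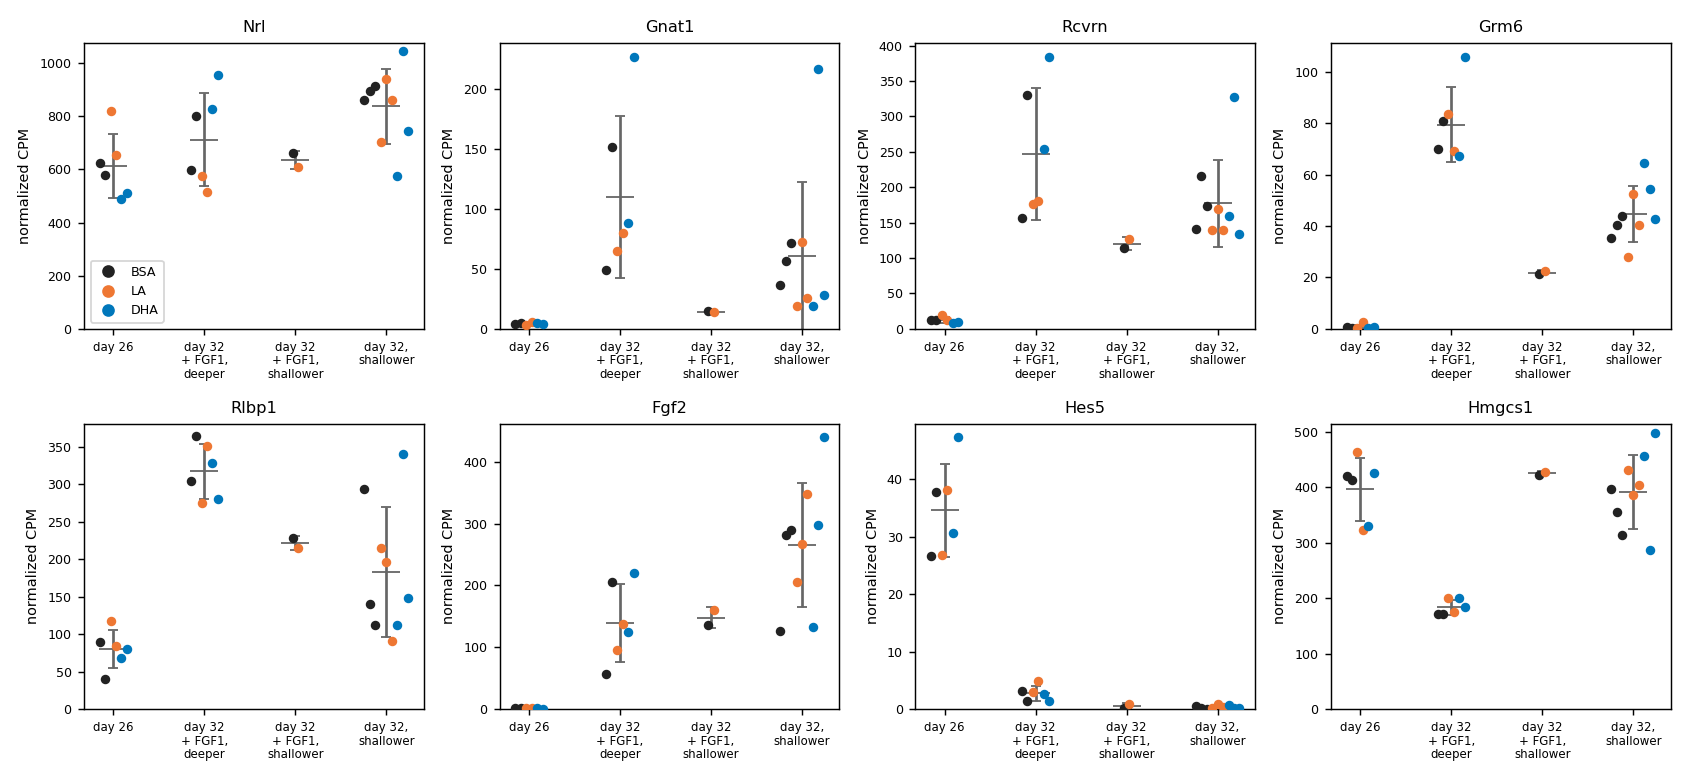
CPM of selected genes in each library by day, FGF1 state and library set. The 2 shallower libraries with FGF1 are drawn apart from the 6 deeper ones.

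Cell type lists moved the same way within the deeper libraries by camera, though none held with an estimated correlation. Higher with day 32 were rods (18 up and 0 down of 20, median 1.65, camera adjusted p = 5.9e-13), shared photoreceptor genes (21 up and 3 down of 26, median 0.76, adjusted p = 1.4e-08), the ribbon synapse (13 up and 0 down of 18, 15 up over the list alone, median 0.70, adjusted p = 7.0e-08) and the primary cilium (12 up and 2 down of 25, median 0.27, adjusted p = 0.0184). Their adjusted p values were 0.208, 0.208, 0.208 and 0.426 with an estimated correlation. Cnga1 (2.82) and Reep6 (1.71) led the rods beside Slc24a1, Rdh12 (2.88) and Aipl1 (2.15) the shared genes, and Cplx4 (2.42) and Slc17a7 (1.66) the synapse. Müller glia (14 up and 0 down of 19, median 1.26, adjusted p = 6.9e-08), reactive gliosis (16 up and 0 down of 16, median 2.55, adjusted p = 5.0e-11), bipolar cells (12 up and 1 down of 18, 13 up over the list alone, median 1.16, adjusted p = 8.0e-09) and horizontal cells (6 up and 1 down of 9, median 0.59, adjusted p = 0.0170) were higher too. With an estimated correlation these gave adjusted p values of 0.256, 0.208, 0.0839 and 0.256. Kcnj10 (3.72) and Slc1a3 (2.32) led the glia, Scgn (4.14) and Grik1 (2.02) the bipolar cells beside Grm6, and Prox1 (1.15) the horizontal cells, where Onecut1 was lower (−1.50).

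Progenitor and division genes went the other way. Progenitors (2 up and 14 down of 19, median −0.66, adjusted p = 2.4e-05) and proliferation (0 up and 18 down of 23, 19 down over the list alone, median −0.67, adjusted p = 5.7e-09) were lower, with Ccnd1 (−0.98), Ccnb1 (−1.57), Top2a (−1.49) and Bub1 (−1.22) among the smallest p. Amacrine genes were lower by camera (3 up and 8 down of 17, 11 down over the list alone, median −0.61, adjusted p = 0.0184), led by Ptf1a (−5.80) and Th (−1.63), though not by fry (adjusted p = 0.0610). With an estimated correlation the 3 lists gave adjusted p values of 0.208, 0.357 and 0.651. Cholesterol synthesis genes fell (1 up and 13 down of 23, 15 down over the list alone, median −0.45, adjusted p = 1.0e-05, and 0.357 with an estimated correlation), with Hmgcs1 (−1.09), Fdps (−1.05), Nsdhl (−0.88) and Idi1 (−0.87) at the smallest p. Targets of FGF and ERK feedback rose (12 up and 2 down of 20, median 0.79, adjusted p = 4.2e-04, and 0.242 with an estimated correlation), led by Spry1 (1.92), Spry4 (1.48) and Spry2 (1.44). In all, 13 of 31 lists passed camera, 13 passed fry and 0 passed camera with an estimated correlation.

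The other 18 lists did not pass camera. Cones held 4 up and 6 down of 14 (median −0.48, adjusted p = 0.252), ganglion cells 3 up and 6 down of 18 (−0.32, adjusted p = 0.143), pigment epithelium 1 up and 3 down of 14 (−1.02, adjusted p = 0.175), ciliary margin 1 up and 1 down of 12 (−0.40, adjusted p = 0.438) and lens 3 up and 0 down of 5 (1.37, adjusted p = 0.117). Forebrain genes gave −0.25 (adjusted p = 0.706), mesenchyme 0.39 (3 up and 0 down of 15, adjusted p = 0.117), endothelium and microglia 0.10 (adjusted p = 0.980) and pluripotency 0.00 (adjusted p = 0.809). Fatty acid oxidation and PPAR targets held 7 up and 2 down of 25 (0.04, adjusted p = 0.259), with Acadvl (1.22) higher beside Cpt1a, fatty acid synthesis 5 up and 3 down of 19 (0.12, adjusted p = 0.461) and the handling of DHA 3 up and 2 down of 13 (median −0.04, though the test leaned upwards, adjusted p = 0.809). The NRF2 response gave 0.06 (6 up and 2 down of 18, adjusted p = 0.261), the unfolded protein response 0.19 (6 up and 1 down of 20, adjusted p = 0.117), hypoxia 0.07 (adjusted p = 0.980), p53 targets −0.02 (adjusted p = 0.980) and oxidative phosphorylation −0.12 (1 up and 0 down of 24, adjusted p = 0.706). Retinoid metabolism held 4 up and 6 down of 17 (median 0.09, though the test leaned downwards, adjusted p = 0.594), with Rbp4 (−2.71), Crabp2 (−2.30) and Stra6 (−1.55) lower.

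**Figure D2:**
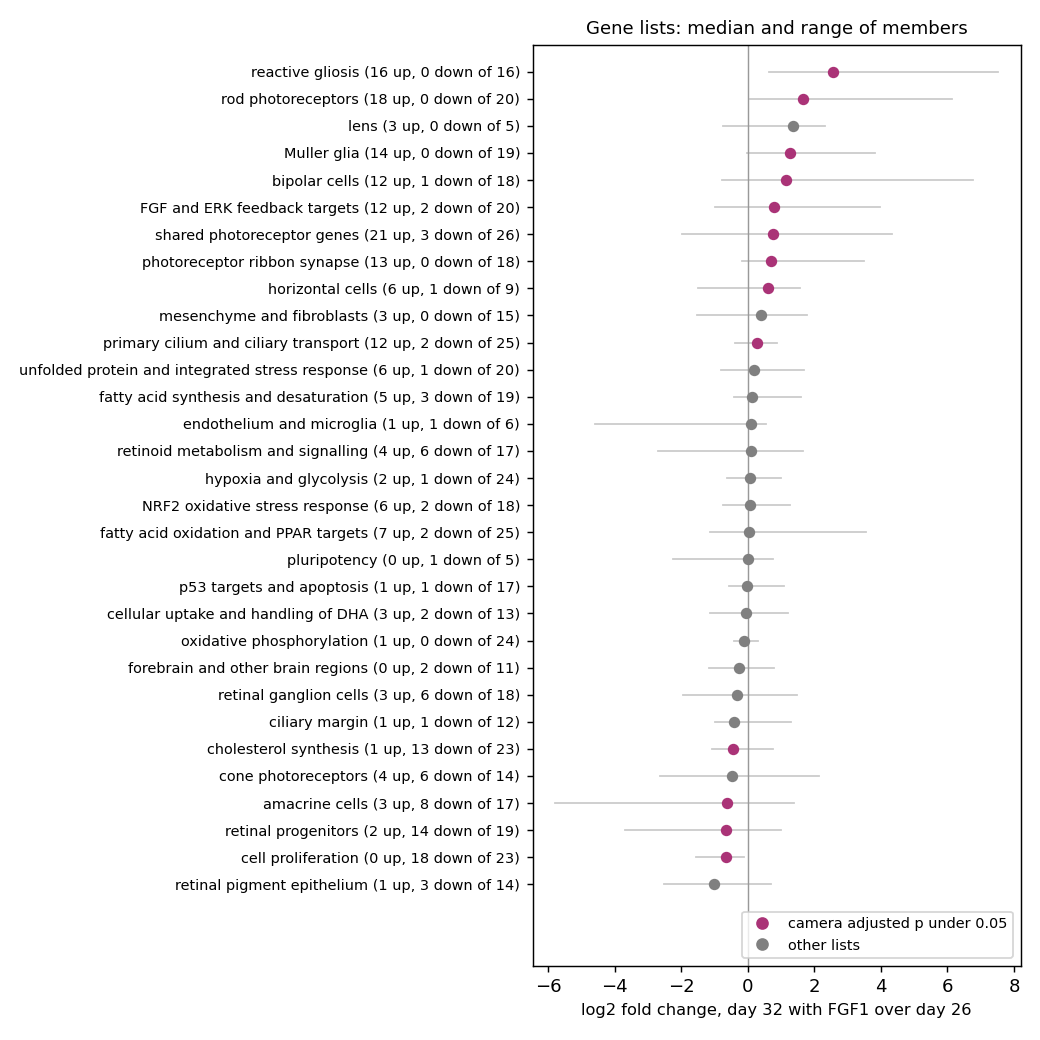
Log2 differences of the members of each gene list, day 32 with FGF1 against day 26 within the 12 deeper libraries.

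Without FGF1, day 32 against day 26 gave many more calls across the depth sets. Rcvrn rose by 3.86 (SE 0.284, adjusted p = 8.4e-08) and Gnat1 by 3.73, as within the deeper libraries, but Hmgcs1 differed by only −0.02 (adjusted p = 0.960). Averaged over media, 6219 genes were higher and 6626 lower (12845 of 21124, edgeR QL, BH), and with library set as a term 349 were higher and 190 lower. That term tells deeper from shallower libraries only through the 2 shallower FGF1 libraries, both left out by the authors. Opn1sw (−4.10), Plin2 (−1.62), Angptl4 (−1.45), Fads2 (−1.39) and Pax6 (−0.81) fell and Rlbp1 (1.21), Dusp6 (1.19), Spry4 (0.96), Etv5 (0.73), Cpt1a (0.70), Scd1 (0.52), Nrl (0.47) and Crx (0.32) rose, whereas Nr2e3 (−0.35) and Arr3 (−0.43) did not pass. The largest differences again included pseudogenes: Nudc-ps1 (10.46), H3f3c (10.40), Hist2h3c1 (10.06), Cbx3-ps7 (9.42), Rpl3-ps1 (9.15), Rps13-ps1 (8.92), BC002163 (8.60), Rpl9-ps4 (8.46), Pcna-ps2 (8.44) and Rps3a2 (8.11) higher, and AY036118 (−14.40), Rpl10a-ps1 (−11.53), Pgam1-ps2 (−10.43), Mrip-ps (−9.73), Oaz1-ps (−8.12), Trex1 (−8.04), Rpl36 (−7.71), Nrarp (−7.44), Nadk2 (−7.06) and Epha8 (−6.47) lower. Except for Rpl9-ps4, Rps3a2, Rpl36 and Epha8, each was at 0 CPM in all libraries of at least 1 group compared, so the fitted values depend on the prior count. Rps13-ps1, Rps3a2 and Pcna-ps2 stood at 79.3, 164.9 and 9.48 CPM in the 3 left-out libraries of day 32 without FGF1, against 0, 0.186 and 0.256 in the 6 kept ones and 0.0884, 0.194 and 0 at day 26, so their rises rest on the left-out libraries. Bipolar genes (13 up and 2 down of 18, median 1.64, adjusted p = 5.3e-06) were the 1 list of 8 past camera that held with an estimated correlation (adjusted p = 0.00282), though not in the 18 libraries kept by the authors (adjusted p = 0.160). Rods gave 11 up and 1 down of 20 (median 0.53, adjusted p = 0.00175, and 0.568 with an estimated correlation).

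In single media the counts of the day comparison without FGF1 hung on single libraries. In BSA 736 genes were higher and 755 lower (1491 in all, DESeq2 4558, limma voom 12333), with Otor (8.80), Fgf2 (6.82) and Grm6 (6.42) the largest rises and AY036118 (−16.77), Rpl10a-ps1 (−15.15) and Oaz1-ps (−11.89) the largest falls. The BSA count was 144 without replicate 1 and 42 without replicate 2 of day 26, and 342 without replicate 2 and 340 without replicate 3 of day 32. In LA 1685 were higher and 2959 lower (4644 in all, DESeq2 7494, limma voom 10953), with Scn7a (7.81), Fgf2 (7.07) and Otor (6.46) against AY036118 (−16.35), Rpl10a-ps1 (−15.06) and Nadk2 (−11.46). The LA count was 186 without replicate 1 and 151 without replicate 2 of day 26, and 737 without replicate 1 and 517 without replicate 3 of day 32. In DHA 1709 were higher and 2137 lower (3846 in all, DESeq2 6884, limma voom 11129), with Apol7e (9.11), Bhlhe23 (7.50) and Fgf2 (7.46) against AY036118 (−10.08), Arvcf (−9.58) and Mrip-ps (−9.57). The DHA count was 693 without replicate 1 and 225 without replicate 2 of day 26, and 1343 without replicate 1, 7454 without replicate 2 and 916 without replicate 3 of day 32. Otor in BSA, Apol7e and all the genes with the largest falls but AY036118 in DHA had a group at 0 CPM in all libraries, so their values depend on the prior count, and Nadk2 and Arvcf have more than one record in the annotation and are uncertain.

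DHA with FGF1 against BSA alone joined both supplements in one contrast. Rcvrn was 0.85 [−0.02, 1.72] log2 units higher, while Nrl differed by 0.00 [−0.53, 0.54] and Crx by −0.07 [−0.51, 0.36], and none of them passed. With edgeR QL and BH 0 of 21124 genes passed (5693 with unadjusted p under 0.05, DESeq2 483, limma voom 10264), with the smallest p for Bmp2 (−2.68), Mecom (−2.64) and Gtse1 (2.53), each with adjusted p = 0.172. Camera passed 0 lists. The BSA libraries were shallower and the DHA with FGF1 libraries deeper.

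The effects of FGF1 and of day were not shown to depend on the fatty acid. The FGF1 effect in DHA against that in BSA differed for 0 of 21124 genes (edgeR QL, BH, 422 with unadjusted p under 0.05, DESeq2 13, limma voom 0), with Hspa12b (−2.36), Zfp133-ps (−2.10) and Fam198b (2.60) at the smallest p. For DHA against LA it differed for 0 genes (416, DESeq2 20, limma voom 0), with Apobec3 (−6.29), Ecel1 (−7.33) and Rpl23a-ps3 (−17.02), a pseudogene at 47.9, 0 and 11.9 CPM in the 3 DHA libraries without FGF1 and at 140.5 CPM in 1 of 3 libraries of LA with FGF1, so that its value is uncertain. The day effect differed between DHA and BSA for 0 genes (211, DESeq2 2, limma voom 0), with Sema3d (2.54), Abca13 (3.62) and Bmp2 (−1.90). Camera passed 1 list for the FGF1 effect in DHA against BSA, rods (median 0.43, adjusted p = 0.0345, and 0.739 with an estimated correlation). It passed 8 lists for DHA against LA, led by rods (0.40, adjusted p = 5.9e-04, and 0.635 with an estimated correlation) and mesenchyme (−1.27, adjusted p = 5.9e-04, and 0.607). It passed 16 for the day effect, led by pigment epithelium (−1.05, adjusted p = 2.8e-08, and 0.0756 with an estimated correlation). With an estimated correlation, and by fry, 0 lists held in each. Both DHA libraries with FGF1 were deeper, while BSA and LA with FGF1 each held a shallower library, so the differences between FGF1 effects mix the sets. The median standard error of 0.602 to 0.634 leaves room for differences of more than 2-fold.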

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

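The fit with library set as a term was chosen after the data had been seen, and the tests of differences between effects were chosen before.

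For the differences of the FGF1 and day effects between media, lists passed camera with its preset correlation, but not the stricter list tests. The FGF1 effect in DHA against that in BSA differed for 1 list, rods (median 0.43, camera adjusted p = 0.0345), the FGF1 effect in DHA against that in LA for 8 lists, and the day effect in DHA against that in BSA for 16 lists. Camera with an estimated correlation and fry each gave 0 lists in all of these comparisons, and edgeR QL gave 0 genes (422, 416 and 211 with unadjusted p under 0.05, DESeq2 13, 20 and 2). DHA with FGF1 held deeper libraries only, while BSA and LA with FGF1 each held a shallower library, so the differences between FGF1 effects mix the sets. With library set as a term the lists past camera numbered 9, 8 and 14, and with the 18 libraries kept by the authors 3, 6 and 6. The lists rest on groups of 2 or 3 libraries. The preset correlation of 0.01 between members may understate their spread. With an estimated correlation in its place 0 lists passed. How the effects differ between media was not settled by these tests.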

How the results depend on the processing

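The fits with library set as a term, with GC offsets, on libraries of one depth set only, with a replicate block within each day and FGF1 state, and all fits of the 5 added comparisons were chosen after the data had been seen.

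RLE size factors left all counts within 1.5 times those reported. The counts for day within the deeper libraries stayed within 1.5 times under each alternative run. The other settings moved the following counts of genes, and where the construction of a setting does not show it, the cause was not tested. DESeq2 gave 2, 1 and 2 genes for DHA against BSA, LA against BSA and DHA against LA at day 26, 5, 2 and 7 at day 32, 54 for DHA against LA with FGF1, and 2, 12 and 10 within blocks. It gave 18, 1727 and 4420 for FGF1 in BSA, LA and DHA, 10 for FGF1 within the shallower libraries, 483 for DHA with FGF1 against BSA, 4558, 7494 and 6884 for day in BSA, LA and DHA, and 13, 20 and 2 for the differences between effects. Limma voom with sample quality weights gave 38 for DHA against LA with FGF1, 48 for LA against BSA and 125 for DHA against LA within blocks, 10660, 11464 and 10583 for FGF1 in BSA, LA and DHA, 14761 for FGF1 averaged over media, 10264 for DHA with FGF1 against BSA, and 12333, 10953 and 11129 for day in BSA, LA and DHA. Without a filter on low counts, day gave 723, 2280 and 2187 genes in BSA, LA and DHA, and FGF1 within the shallower libraries gave 32.

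The 18 libraries kept by the authors gave 1 gene for DHA against BSA at day 32, 7896, 8730 and 6267 for FGF1 in BSA, LA and DHA, 7813 for DHA with FGF1 against BSA, and 8995, 9019 and 8113 for day in BSA, LA and DHA. In these libraries each contrast of FGF1 or of days without FGF1 is also one of deeper against shallower libraries. The groups of the comparison only gave 2 for DHA against BSA and 1 for DHA against LA at day 26, 7427 for DHA with FGF1 against BSA, and 9145 and 7913 for day in BSA and LA. Library set as a term gave 0 for FGF1 averaged over media (1274 with unadjusted p under 0.05), 539 for day averaged over media, and 170, 67 and 406 for day in BSA, LA and DHA. Only the shallower libraries of BSA with FGF1 and of LA with FGF1, both left out by the authors, share a group with deeper ones. The part of that term between deeper and shallower libraries rests on them. GC offsets gave 3308 for FGF1 averaged over media and 1963 and 2504 for day in LA and DHA. Libraries of one depth set only gave 2 genes for DHA against LA with FGF1.

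The replicate numbers in the titles were checked for pairing by correlating residuals between groups. They gave r of −0.121 to 0.219 at day 26 (2 of 6 pairs over 0.1), −0.0156 to 0.832 with FGF1 (6 of 7), −0.302 to 0.546 at day 32 without FGF1 (5 of 9) and −0.341 to 0.631 across FGF1 states (11 of 24). At day 26 the residuals of the 2 libraries of a group mirror each other. Replicates 1 and 2 there give the same r by construction and are not separate evidence. Every pair was over 0.1 for DHA with LA at day 32 without FGF1, and for BSA with LA among libraries with FGF1 (0.693 to 0.832), where replicate 3 is the shallower library of both groups. For DHA with LA, replicate 1 of both groups was left out by the authors. Replicate 2 had the lowest score of its group on the first principal component (53.5 in LA, 11.6 in DHA). Library set and GC content may thus also give these correlations, which was not tested. Elsewhere at least 1 pair was at 0.1 or lower, or there were fewer than 3 pairs, so the samples of those groups share only a number. The replicate block gave 13, 2304 and 8 genes for FGF1 in BSA, LA and DHA and 14 for DHA with FGF1 against BSA. A replicate block within each day and FGF1 state gave 2 genes for DHA against BSA and 2 for DHA against LA at day 32.

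Leaving out 1 library at a time, where a group of 2 is left with 1 library that is assumed to vary like the other groups, gave 42 (without day 26 BSA replicate 2) to 1234 genes for day in BSA, 151 (without day 26 LA replicate 2) to 5566 (without LA replicate 2) for day in LA and 225 (without day 26 DHA replicate 2) to 7454 (without DHA replicate 2) for day in DHA. It gave 0 to 7936 genes for FGF1 in LA (without LA with FGF1 replicate 3), 0 to 5752 for FGF1 in DHA (without DHA replicate 2), 6381 to 12022 for FGF1 averaged over media, 11315 to 13302 for day averaged over media and 4373 to 5922 for day within the deeper libraries. All other counts were 0 without any single library.

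Named genes kept their direction and their side of the threshold in 3222 cases, became stronger in 75, weaker in 196 and changed sign in 18, of which 17 came with library set as a term. With GC offsets Ncaph2 gave −0.26 for FGF1 in DHA. With library set as a term FGF1 averaged over media gave Pgam1-ps2 −0.21, Rpl36 −1.54, Nadk2 −5.08, Hgs −1.20, Rpl3-ps1 0.12, Cd247 0.22 and Mkks 0.26. Day in LA gave Nadk2 0.0904, day in DHA gave AY036118 0.21, and day averaged over media gave Nudc-ps1 −0.44, H3f3c −1.48, BC002163 −0.55, Rpl9-ps4 −1.79, Pcna-ps2 −1.21, Rps3a2 −4.95, Rpl36 0.49 and Nadk2 4.51. Camera with an estimated correlation passed 0 lists for day within the deeper libraries, where fry passed 13. The shallower libraries had at least 1 count for 23494 genes (kept by the authors) and 23183 genes (left out) on average, against 27344 in the deeper ones, and whether depth made this difference was not tested.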

Other observations

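The tests of library set, of FGF1 as the whole cause, of GC content as the whole or a part of the cause, of library depth, of another genetic background and of a Y chromosome were chosen after the result had been seen, and the tests on splits of the libraries, on GC content and on mesenchyme for the 5 left-out libraries were chosen before.

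Within the deeper libraries, where FGF1 and the medium changed with age, 16 of 16 reactive gliosis genes rose between day 26 and day 32. The list passed camera (adjusted p = 5.0e-11) but not with an estimated correlation (adjusted p = 0.208). Fgf2 stood at 1.90 ± 0.515 CPM at day 26 (n = 6), 140 ± 63.1 in the 6 deeper libraries with FGF1, 148 in the 2 shallower ones and 265 ± 99.9 in the 9 libraries without FGF1 (321 in the 6 kept by the authors, 155 in the 3 left out). Its rise was also seen without added FGF1, though only across the depth sets. Edn2 stood at 0.0530, 10.1 ± 5.92, 1.26 and 2.98 CPM in the same order. Hes5 fell from 34.5 ± 8.02 CPM to 2.73 ± 1.28, 0.541 and 0.389, and Grm6 rose from 0.839 ± 0.822 CPM to 79.5 ± 14.6, 21.9 and 44.7 ± 10.9, so both moved the same way in each set of day 32 libraries. Hmgcs1 did not: it stood at 396 ± 56.8 CPM at day 26, 184 ± 13.3 in the deeper libraries with FGF1, 425 in the shallower ones with FGF1 and 393 ± 66.7 in those without FGF1. With library set as a term 12 lists passed camera for day averaged over media, and bipolar genes (median 1.25), horizontal cell genes and shared photoreceptor genes held with an estimated correlation (adjusted p = 7.5e-04, 0.0490 and 0.0490). That term tells deeper from shallower libraries only through the 2 shallower FGF1 libraries, both left out by the authors, so these results rest on them.

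The day 32 libraries with and without FGF1 lay apart in many genes. On 11977 genes called in the 18 libraries kept by the authors, the 2 shallower FGF1 libraries were placed between the shallower libraries without FGF1 (0) and the deeper libraries with FGF1 (1). Their median positions were −0.204 and −0.102, beside the shallower libraries without FGF1, which argues against FGF1 as the whole cause and is consistent with the library set as the cause. Both are among the 5 libraries left out by the authors, so these positions rest on libraries that are in doubt themselves. The first principal component correlated with the GC slope per library (absolute r 0.998), so set and GC content run together. With GC offsets 2470 of the 9536 genes (25.9%) were still called, which argues against GC content as the whole cause for these genes. The other 7066 calls ended, the median absolute log2 difference of the 9536 genes dropped from 1.04 to 0.374, and a median share of 0.301 of the log2 difference was left (quartiles 0.0707 and 0.557). This is consistent with GC content as a part of the cause. What made the sets differ (a sequencing or library batch is a candidate explanation) is not given by the labels and stays open, and so does an FGF1 effect smaller than the difference between the sets.

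The 5 libraries left out by the authors held transcripts that the other 18 nearly lacked, Y-linked ones and Meg3 among them. Library depth was excluded, since the lowest Eif2s3y level among the 5 was 37.3-fold the highest among the 6 kept shallower libraries. GC content was excluded, since Eif2s3y still differed by 6.92 (SE 0.349) with GC offsets. The mesenchyme list differed by a median of only 0.351 (upper quartile 0.612), which argues against a large share of RNA from fibroblasts or other mesenchyme. A small admixture cannot be excluded by this test, since the 6 kept shallower libraries already held such transcripts (Col3a1 at a mean of 21.3 CPM). Cells of another genetic background stay open: 44 autosomal genes of 19340 outside the Meg3 region had all 5 libraries over 4 times the highest of the other 18, against at most 2 for any other choice among 462, but a batch or any admixture shared by the 5 would give this too. Cells carrying a Y chromosome also stay open, with 2 of 4 Y-linked genes above the other libraries in all 5.

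Other splits of the libraries tested whether chance could give as many genes. For FGF1 averaged over media 1 of 100 splits within each medium, the real one, gave at least as many genes (9536, highest other 5851). The same held for day averaged over media, 1 of 100 (12845, highest other 8887), and for day within the deeper libraries, 1 of 100 (5797, highest other 1205). A random regrouping of the labels is thus an unlikely source of these counts. The splits do not tell FGF1, or day averaged over media, from the depth sets. The real labels placed 15 of 17 libraries by set for FGF1 and 15 of 15 for day. The split with 8887 genes placed 13 of 15 libraries by depth set. The split with 5851 genes placed only 7 of 17 by set, while 3 splits that placed 13 of 17 by set gave 0 genes, so what it follows stays open. For DHA against BSA, LA against BSA and DHA against LA within blocks the real count was 0, which all 100 splits reach by construction (highest other 2, 1 and 1), so these splits say nothing about chance. For groups of 3 against 3, 10 splits are too few for a share under 0.05: the real counts were 0, and the highest others 1 for DHA against BSA, 0 for LA against BSA and 2 for DHA against LA at day 32, 0 for FGF1 in BSA and 7557 for FGF1 in LA. That last split placed replicates 1 and 2 of LA with FGF1, which are the deeper libraries, with LA replicate 2, against 3 shallower libraries. The deeper pair with any other library of the comparison gave 0 genes, so depth set alone does not explain the count. LA replicate 2 lay towards the deeper libraries on the first principal component, which follows the GC slope. Its score was 53.5, against 137, 144 and 139 for the 3 libraries opposite. Why its GC slope differs stays open.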
